A study of Homo sapiens with 6 samples.

How the data were processed

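RNA was sequenced in 6 libraries from cells labelled as MDA-MB-231, a triple-negative breast cancer line, in 3 groups of 2. Per the labels, the groups are control cells, cells with a stable knockdown of ELK3 given a control plasmid, and the same knockdown cells given a plasmid that carries ELK3. Both plasmid groups received 1 µg of DNA and were collected 48 hours later. Neither value is recorded for the controls, so contrasts with them mix the labelled knockdown with plasmid transfection. The libraries were made with a kit that reads the ends of transcripts. Whether replicates are separate cultures or repeats of the same culture is not stated, so the p-values may measure technical spread only.

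The deposited values are raw counts, reads per gene symbol and library, with no scaling. The authors' notes name Bowtie2 for alignment, edgeR and the hg19 genome without versions. The counting tool, the annotation and any filter are not stated. Each file holds 25737 lines with 24462 distinct symbols. Lines that share a symbol, 1561 lines of 286 symbols, were summed. No transcript of the mitochondrial genome is listed, so the list of those transcripts, fixed with the others, had 0 genes in the files. Every library was checked for its total and for the agreement of its replicates. Within a group the spread of counts exceeded counting error by a chi-square per degree of freedom of 2.21 to 3.02.

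Library totals ranged from 4884483 to 9131214 counts. A count of 3, the upper limit that 0 counts allow at 95% confidence, stands for 0.329 to 0.614 counts per 1000000 (CPM) in a single library. Folds against a group with 0 counts were computed against 3 counts over the group and are lower bounds. With 1 to 3 counts, the ratio is given with its exact 95% counting interval. The library labels do not mention molecular identifiers, and intervals and floors cover counting error only.

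Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes passing filterByExpr were kept, 15386 in all. Libraries were scaled by TMM, and 1 robust quasi-likelihood model with a mean per group was fitted to all 6 libraries with 3 residual degrees of freedom. The common biological coefficient of variation was 0.065. For 3 contrasts, p-values were two-sided and adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. Log2 fold changes are given with their SE from the fit. CPM values are TMM-scaled and given as mean and SD over n = 2 libraries. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the plots.

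Before the data were examined, 32 gene lists were fixed, of which 31 had at least 5 tested genes. They cover mitochondrial dynamics and metabolism, NK-cell and T-cell ligands, targets of SRF and its cofactors, invasion, stress and cell cycle, with markers of lymphocytes, luminal breast cells, fibroblasts and endothelial cells. Lists were tested with camera of limma on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. The same test was run with a correlation estimated per list. No list passed 0.05 with an estimated correlation in any contrast, and 3, 3 and 5 lists had an unadjusted p under 0.05 there. That form of camera uses the 3 residual degrees of freedom, which makes it hard to pass. NF-kappaB targets had an estimated correlation of -0.018, below the preset 0.01. Their camera p between knockdown with control plasmid and controls still went from 3.7e-06 to 0.0142. Not passing there does not by itself show correlation among a list's genes. Fry, which asks whether a list's genes move, was run beside camera.

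The genes named were set by a rule fixed in advance. It takes ELK3, then per contrast the 10 highest and 10 lowest log2 fold changes among genes past the threshold, with at least 5 CPM in the higher group and both libraries of a group above both of the other. Up to 4 members per list, by smallest p, and a fixed panel of genes could be named besides. For genes called in opposite directions it takes the 5 each way with the largest smaller change. In these selections by fold change, genes with LOC names were skipped, as the rule states. The transcripts XIST and TSIX were left out as well, which the rule does not state.

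Alternatives were a replicate block, DESeq2 size factors, library totals without scaling, DESeq2, limma-voom, no filter, a filter of 10 CPM in 2 libraries, only the 4 libraries compared, and each library left out in turn. Alternatives added after seeing the data were an exchange of the knockdown labels, leaving out symbols on several lines, and giving each of a pair of contrasts its own library of the group they share. Pseudocounts for normalised values did not apply to counts. The test was tried on simulated data built from the fit. It recovered 82 of 100 genes changed by 1 log2 unit and 95 of 97 changed by 2 between the first pair of groups, with 9 false calls among 186. In the other contrasts it recovered 78 of 98 and 94 of 96, and 77 of 98 and 95 of 97. Only 200 genes were changed there, far fewer than were called in the data, so these rates need not carry over. A raised list had an adjusted p of 3.44e-51 and a p of 0.000403 with an estimated correlation, and 0 of 200 unchanged lists were called. The covariance and correlation that a shared group gives by itself were measured in 100 simulations of unchanged groups. No other files were left out.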

Results

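The data are RNA-seq counts from cells labelled as the breast cancer line MDA-MB-231, in 3 groups of 2 libraries. They are control cells, cells labelled as an ELK3 knockdown with a control vector (vector-labelled libraries) and cells labelled as the knockdown with re-expressed ELK3 (ELK3-labelled libraries). Totals were 5087967 and 5028028 counts in the controls, 6669969 and 4884483 in the vector-labelled libraries, and 5960518 and 9131214 in the ELK3-labelled libraries. Between 17976 and 20360 genes were detected per library. Pearson's r of log2 CPM across genes, which are not independent replicates, was at least 0.993 within groups and 0.917 to 0.964 between groups. Albumin (ALB), a protein made by the liver, stood at 3011 to 3986 CPM in every library.

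ELK3, an ETS-family transcription factor that binds DNA with SRF, was the gene targeted. In the GENCODE 29 annotation of GRCh38 it lies on chromosome 12 from 96194382 to 96269835 on the plus strand. The control libraries held 128.6 and 123.9 CPM of ELK3 (615 and 576 counts). The libraries labelled knockdown with control vector held 758.9 and 697.2 CPM (5166 and 3484 counts). The libraries labelled knockdown with ELK3 held 20.4 and 22.6 CPM (128 and 213 counts). ELK3 thus ran against the labels: it was 5.77-fold higher than the controls where a knockdown is labelled and 5.83-fold lower than the controls where re-expression is labelled. The log2 fold changes were 2.53 ± 0.09 (adjusted p = 1.6e-22) and -2.54 ± 0.11 (adjusted p = 3.53e-20). Every direction given here follows the labels as deposited, and the names vector-labelled and ELK3-labelled do not describe the ELK3 level measured.

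**Figure D1:**
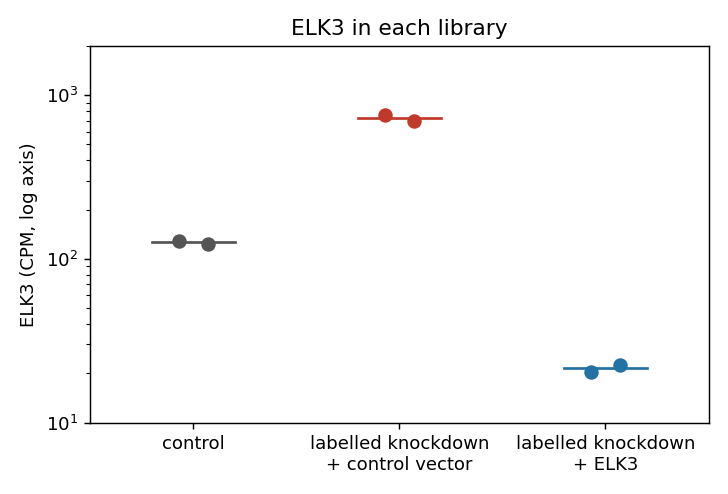
ELK3 in CPM on a log axis for each of the 6 libraries, with 1 point per library and a line at each group's mean. The vector-labelled libraries sit at 758.9 and 697.2 CPM, above both controls, and the ELK3-labelled libraries at 20.4 and 22.6 CPM, below both.

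Comparing vector-labelled libraries with controls asks what the labelled knockdown and the plasmid transfection changed together. The controls have no recorded transfection, so these cannot be told apart. For the genes and lists of this comparison, a possible difference in cell line cannot be told apart from them either. Several abundant genes of the controls were far lower in the vector-labelled libraries, where ELK3 was higher. PLAU, the urokinase that activates plasmin, had 8.26 ± 1.2 CPM against 427.1 ± 5.83 in the controls, 50.9-fold lower (adjusted p = 6.09e-28). The receptor kinase AXL was lower by a log2 fold change of -5.48 ± 0.12, and CXCL8, the neutrophil chemokine interleukin-8, by -5.97 ± 0.2. Of 15386 genes tested, 5688 rose and 5429 fell, of which 3649 and 2984 changed at least 2-fold. By the fitted fold change, 1028 rose and 299 fell at least 8-fold. In the same libraries, 28 of 28 genes chosen after the values were seen as typical of MDA-MB-231 cells fell (median log2 fold change -2.19), and 20 of 22 chosen as typical of the embryonic kidney line HEK293 rose (median 2.56).

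The 10 genes with the highest fold changes had 0 counts over both controls and 5.32 to 12.3 CPM in the vector-labelled libraries, so they were at least 17.8-fold to at least 39.2-fold higher. They included the synaptic vesicle release genes RIMS1 and UNC13A, the efflux transporter ABCB5, the transcription factor gene GLIS1, TRIM43B, FSTL4, MGAT4C, the small heat-shock gene HSPB3 and the cone photoreceptor gene PDE6C. Among the 10 lowest were KRT7, a keratin of simple epithelia (-6.0 ± 0.22), and NOG, the BMP antagonist noggin (-6.31 ± 0.3), with CXCL8 and PLAU. Also among them were ADTRP and the non-coding RNAs LINC00960, LINC00601, FAM225A and PRRT3-AS1, with 1 or 2 counts in the vector-labelled libraries. Their ratios ran from 57.6 (95% counting interval 15.5 to 483, PRRT3-AS1) to 116 (20.4 to 4650, LINC00960). The largest adjusted p among these 20 genes was 2.1e-07. TRIM43B has near-identical copies in the genome, and how reads shared between copies were counted is not stated.

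Of 25 NF-kappaB targets and cytokines, 20 fell, 2 rose and 3 were not called (median -2.69). IER3, an early response gene, fell from 1737 to 64.5 CPM, and CSF1, the macrophage growth factor, by -2.63 ± 0.15. Camera gave an adjusted p = 0.000115, and an adjusted p = 0.215 with an estimated correlation. Of 26 cytoskeletal targets of SRF and MRTF, 19 fell and 4 rose, and of 32 genes of hypoxia and glycolysis 23 fell and 2 rose. Both lists had an adjusted p = 0.000643, and an adjusted p = 0.215 with an estimated correlation. Examples are the actin cross-linker ACTN1 (-3.29 ± 0.1), the muscle ankyrin-repeat gene ANKRD1 (-3.65 ± 0.1), the lactate exporter SLC16A3 (-4.31 ± 0.16) and the angiogenic factor VEGFA (-2.62 ± 0.11). Of 28 immediate early genes bound by SRF and ternary complex factors, 17 fell and 6 rose (adjusted p = 0.0448, and adjusted p = 0.467 with an estimated correlation). The AP-1 subunit FOSL1 fell by 5.27 on the log2 scale and ATF3, a stress-induced factor, rose by 2.86 ± 0.1. Of 32 mesenchymal genes, 19 fell and 10 rose (adjusted p = 0.0484, and adjusted p = 0.343 with an estimated correlation). The hyaluronan receptor gene CD44 and the intermediate filament gene VIM had log2 fold changes of -2.81 ± 0.1 and -2.14 ± 0.08. The immediate early call ended without control replicate 2 (adjusted p = 0.0569) and without vector-labelled replicate 2 (0.0755). The mesenchymal call ended without control replicate 1 (0.0557), control replicate 2 (0.0561) and vector-labelled replicate 2 (0.0537), and with the replicate number as a block (0.0517).

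Mitochondrial dynamics is named in the series title. Of 17 fission genes, 13 fell, 2 rose and 2 were not called (median -0.6, adjusted p = 0.041, and adjusted p = 0.343 with an estimated correlation). That call ended without control replicate 2 (adjusted p = 0.0561). INF2, a formin that assembles actin at mitochondria, had a log2 fold change of -2.66 ± 0.27 and the outer membrane protein gene SLC25A46 -1.63 ± 0.15. DNM1L, the dynamin-related GTPase of fission, fell from 67 to 54.6 CPM and its adaptor FIS1 from 45.8 to 26.9 CPM. The DNM1L call ended without vector-labelled replicate 1 (adjusted p = 0.0881), with library totals (0.172), with a filter of 10 CPM (0.0949) and with DESeq2 (0.0584). MFF, another adaptor, had a log2 fold change of -0.11 ± 0.12 (0.02 with library totals) and was not called. Of 18 genes of fusion and cristae shaping, 8 rose and 8 fell (adjusted p = 0.943, median -0.09, and 0.05 with library totals alone). The fusion GTPase genes MFN1 and OPA1 fell by 1.03 and 0.85 on the log2 scale, and MFN2 rose by 0.79 ± 0.1. Of 21 genes of mitochondrial DNA upkeep and biogenesis, 16 fell and 2 rose (adjusted p = 0.0113, and adjusted p = 0.343 with an estimated correlation). The nuclear receptor gene ESRRA had a log2 fold change of -2.77 ± 0.09 and TFAM, which packages mitochondrial DNA, -1.48 ± 0.09. Of 77 mitochondrial ribosomal proteins, 42 fell and 17 rose (adjusted p = 0.0245, and adjusted p = 0.461 with an estimated correlation), with MRPL33 at -2.37 ± 0.11 and MRPL18 at 2.56 ± 0.1.

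The higher lists were cholesterol synthesis, with 17 of 24 genes up and 4 down (adjusted p = 0.0245, and adjusted p = 0.343 with an estimated correlation), and p53 targets, with 18 of 25 up and 3 down (adjusted p = 0.041, and adjusted p = 0.467 with an estimated correlation). HMGCS1 and SQLE, enzymes of sterol synthesis, rose by 1.99 ± 0.1 and 2.25 ± 0.12. The p53 antagonist gene MDM2 rose by 1.87 ± 0.1 and the sestrin gene SESN1 by 3.08 ± 0.17. The p53 call ended without control replicate 2 (adjusted p = 0.0638). Ligands of activating NK receptors, 12 down and 6 up of 21, had an adjusted p = 0.378. The NKG2D ligand genes MICA and MICB fell from 53.1 to 4.55 and from 108.9 to 29.6 CPM, and PVR, a ligand of DNAM-1, from 180.2 to 62.2 CPM. Of 23 genes of HLA class I presentation, 14 fell and 4 rose (adjusted p = 0.0565), and this list passed the threshold without control replicate 1 (0.0374) and without either ELK3-labelled replicate (0.0453 and 0.0444). HLA-B had a log2 fold change of -0.87 ± 0.09 and HLA-C 0.2 ± 0.09; HLA genes share near-identical sequence. The HLA-C call ended without any library but control replicate 1, at adjusted p of 0.261 without control replicate 2, 0.214 and 0.0685 without either vector-labelled replicate and 0.0546 and 0.0563 without either ELK3-labelled replicate. It also ended with DESeq2 (0.0765) and with no filter (0.169). Adjusted over the list alone, the counts of higher and lower genes differed for 3 of the 31 lists and for 0 of the 10 called here.

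Comparing ELK3-labelled with vector-labelled libraries asks what re-expression changed in the labelled knockdown, with ELK3 itself 33.6-fold lower where re-expression is labelled (-5.07 ± 0.11, adjusted p = 3.63e-28). HIST1H2BG, a replication-dependent histone gene, fell from 51.2 to 1.57 CPM, and BIRC5, the mitotic gene of survivin, from 1139 to 306.5 CPM. In the other direction, SLC25A46 rose from 18.6 to 77.8 CPM. Of 15386 genes, 4615 rose and 4559 fell, of which 1593 and 1901 changed at least 2-fold. By the fitted fold change, 9 rose and 331 fell at least 8-fold. MDA-MB-231-typical genes split, with 9 up and 7 down of 28 (median 0.08), and of 22 HEK293-typical genes 12 rose and 4 fell (median 0.44). Of the 15 HEK293-typical genes whose values had not been looked at before, 8 rose and 2 fell (median 0.84).

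The 10 genes raised most had 5.17 to 45.7 CPM in the ELK3-labelled libraries and adjusted p of at most 2.97e-05. They included the ion channel genes KCNC4 (3.13 ± 0.34) and SCN2A (2.85 ± 0.47), MTERF4, which acts in mitochondrial ribosome assembly (2.57 ± 0.21), and the nuclear receptor gene NR2E1 (2.55 ± 0.48), with ANKEF1, LINC01158, GATAD1, MFAP3, TMEM92 and ZSCAN9. The 10 lowered most had 1 to 8 counts over both ELK3-labelled libraries. Their names were TRIM43B, TRIM43, RFPL4A, RFPL4AL1, GOLGA6C, LINC00368, LVCAT8, the parathyroid hormone gene PTH, the seminal plasma gene MSMB and the sarcomere gene MYPN. RFPL4A fell from 38 to 0.504 CPM. The ratios of the others ran from 90.4 (15.7 to 3620, MYPN) to 195 (34.5 to 7770, TRIM43B). TRIM43, RFPL4A and GOLGA6C have near-identical copies.

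Of 17 fission genes, 14 rose, 2 fell and 1 was not called (median 0.8, adjusted p = 0.00972, and adjusted p = 0.368 with an estimated correlation). MIEF1, a receptor for DNM1L, rose by 1.67 ± 0.1, DNM1L by 0.84 ± 0.1, FIS1 by 0.78 ± 0.13 and MFF by 0.29 ± 0.11. The MFF call ended without vector-labelled replicate 2 (adjusted p = 0.149) and without either ELK3-labelled replicate (0.0566 and 0.0715), with DESeq2 (0.106) and with a filter of 10 CPM (0.0661). Of 38 genes of G2/M and mitosis, 26 fell and 8 rose (adjusted over the list alone, 26 and 9), with an adjusted p = 0.0134, and an adjusted p = 0.368 with an estimated correlation. The mitotic kinase gene AURKA had a log2 fold change of -1.73 ± 0.08 and UBE2C, a ubiquitin carrier of mitotic exit, -1.54 ± 0.09. Of 22 histone genes 13 fell and 3 rose (adjusted p = 0.0134, and adjusted p = 0.368 with an estimated correlation). HIST2H2BE and HIST1H2BD had log2 fold changes of -3.57 ± 0.15 and -3.39 ± 0.13, and histone genes have near-identical copies. Of 24 cholesterol genes 13 fell and 3 rose (adjusted p = 0.03, and adjusted p = 0.517 with an estimated correlation), with the sterol enzymes NSDHL and MVD at -1.51 ± 0.11 and -1.68 ± 0.16. Of 78 cytosolic ribosomal proteins 39 fell and 6 rose (adjusted p = 0.03, and adjusted p = 0.63 with an estimated correlation), with RPS9 at -0.69 ± 0.09. Their median was -0.18. Of 42 liver genes, a list chosen after the values were seen, 32 fell and 0 rose (median -0.32). Cholesterol lost its call without control replicate 1 (0.057), control replicate 2 (0.0566) and ELK3-labelled replicate 1 (0.0711). The ribosomal list lost it without control replicate 1 (0.0616), control replicate 2 (0.0619), vector-labelled replicate 1 (0.0784) and ELK3-labelled replicate 1 (0.174). Fusion and cristae genes had 6 up and 7 down of 18 (adjusted p = 0.994), and NK ligands 5 up and 6 down of 21 (adjusted p = 0.574). Of 21 lymphocyte and NK cell markers 7 fell and 1 rose (adjusted p = 0.0652), with PTPRC, or CD45, at -0.53 ± 0.14 and the protease gene GZMA at -0.45 ± 0.12, a call that ended without vector-labelled replicate 1 (0.0835). Of 21 genes of mitochondrial DNA upkeep and biogenesis 11 rose and 2 fell (adjusted p = 0.0579). The marker list passed 0.05 without vector-labelled replicate 2 (0.0418) or ELK3-labelled replicate 2 (0.0411), and the biogenesis list without vector-labelled replicate 1 (0.0277) or ELK3-labelled replicate 2 (0.0411). MICA rose from 4.55 to 10.8 CPM, and MICB (0.21 ± 0.13) and PVR (-0.14 ± 0.1) were not called.

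Comparing ELK3-labelled libraries with controls asks how far the labelled re-expression, with its plasmid transfection, differs from control cells. AXL and PLAU were lower than in the controls here too, where ELK3 was lower. AXL went from 605.7 to 11 CPM, PLAU from 427.1 to 7.99 CPM and HLA-B from 390.8 to 176.2 CPM. Genes tested numbered 15386, with 4891 higher and 4742 lower, of which 2455 and 1882 changed at least 2-fold. By the fitted fold change, 631 were higher and 345 lower by at least 8-fold. In these libraries, 27 of 28 MDA-MB-231-typical genes fell (median -2.38), and 19 of 22 HEK293-typical genes rose (median 3.13). Here too, a possible difference in cell line cannot be told apart from the labelled treatment in any gene or list.

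Among the 10 highest, TBX2-AS1 had 0 counts in the controls and was at least 20.4-fold higher. The kinesin gene KIF1A had a ratio of 58.6 (16 to 487), the endophilin gene SH3GL2 69.7 (12.3 to 2780), ADAMTS19 49.9 (8.71 to 1990), NR2E1 46.9 (8.17 to 1880), IGDCC3 41.5 (14 to 203) and the growth factor gene FGF9 34.7 (11.7 to 170). The laminin gene LAMA1, the forkhead gene FOXD1 and LINGO1 rose by 4.96 ± 0.37, 4.95 ± 0.24 and 4.86 ± 0.44. Among the 10 lowest, APCDD1L, MARCH4 and LINC01444 had 0 counts in the ELK3-labelled libraries and were at least 62.1-fold, at least 34.9-fold and at least 29.4-fold lower. PLEK2 had a ratio of 243 (66.7 to 2020), LINC00704 149 (50.3 to 725), ZNF93 160 (28 to 6370), ADTRP 113 (19.6 to 4530) and the keratin gene KRT15 110 (19 to 4400). CALB2, the calcium binder calretinin, had a log2 fold change of -6.73 ± 0.31. The largest adjusted p of the 20 was 4.04e-07.

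Of 25 NF-kappaB targets, 22 fell and 1 rose (adjusted p = 2.07e-08, and adjusted p = 0.152 with an estimated correlation), among them CXCL8 at -5.66 ± 0.18 and IER3 at -4.12 ± 0.1. SRF and MRTF targets fell in 19 of 26 and rose in 4 (adjusted p = 0.000219), hypoxia genes fell in 24 of 32 and rose in 4 (0.000588), and G2/M genes fell in 26 of 38 and rose in 6 (0.000722); each had an adjusted p = 0.152 with an estimated correlation. Adjusted over the list alone, 5 hypoxia genes rose. ANKRD1 had a log2 fold change of -3.95 ± 0.1, VEGFA -2.38 ± 0.11 and the cytokinesis gene ANLN -1.6 ± 0.09. Mesenchymal genes fell in 19 of 32 and rose in 9 (adjusted p = 0.0199, and adjusted p = 0.278 with an estimated correlation), with CD44 at -3.36 ± 0.1. Matrix protease and invasion genes fell in 13 of 22 and rose in 4 (adjusted p = 0.0305, and adjusted p = 0.278 with an estimated correlation), with PLAU at -5.71 ± 0.12. That call ended without control replicate 1 (0.0598), control replicate 2 (0.0532) and vector-labelled replicate 2 (0.0544). The p53 targets rose in 18 of 25 and fell in 3 (adjusted p = 0.0019, and adjusted p = 0.329 with an estimated correlation), with MDM2 at 1.53 ± 0.1.

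Immune ligand genes were lower as lists. HLA class I presentation fell in 15 of 23 and rose in 1 (adjusted p = 0.00102, and adjusted p = 0.336 with an estimated correlation). B2M, the light chain of HLA class I, had a log2 fold change of -1.22 ± 0.08, the immunoproteasome gene PSMB8 -3.09 ± 0.17, and HLA-C -0.14 ± 0.09, which was not called. Ligands of activating NK receptors fell in 13 of 21 and rose in 5 (adjusted p = 0.0305, and adjusted p = 0.278 with an estimated correlation), and this call ended without control replicate 2 (0.0585). MICA fell from 53.1 to 10.8 CPM and PVR from 180.2 to 56.2 CPM, and CADM1, an adhesion ligand of CRTAM, rose from 29.4 to 293.2 CPM. Ligands of inhibitory receptors fell in 8 of 13 and rose in 1 (adjusted p = 0.0305, and adjusted p = 0.278 with an estimated correlation), with NT5E, the ectonucleotidase CD73, at -5.44 ± 0.13 and LGALS1, galectin-1, at -3.09 ± 0.09. Fission genes had 8 up and 4 down of 17 (adjusted p = 0.389), with DNM1L at 0.54 ± 0.1, FIS1 at 0 ± 0.13 and MFF at 0.18 ± 0.11, which was called with library totals (0.34, adjusted p = 0.00939). MFN1, MFN2 and OPA1 stood at -0.49 ± 0.14, 0.56 ± 0.09 and -0.72 ± 0.1, and the MFN1 call ended without control replicate 2 (adjusted p = 0.0615). The markers of lymphocytes, luminal cells, fibroblasts and endothelial cells were not called as lists, with adjusted p from 0.134 to 0.806. Of 21 lymphocyte and NK cell markers 7 fell and 2 rose (adjusted over the list alone, 5 and 2; median -0.37), and of 42 liver genes, a list chosen after the values were seen, 34 fell and 0 rose (adjusted over the list alone, 36 and 0; median -0.29). The medians of HLA class I presentation and of the activating and inhibitory ligands were -0.61, -1.05 and -0.63. Antioxidant genes had 5 up and 12 down of 25 (camera adjusted p = 0.0526). Genes of mitochondrial DNA upkeep and biogenesis had 3 up and 12 down of 21 (camera adjusted p = 0.065). Both lists stood near the threshold of 0.05.

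**Figure D2:**
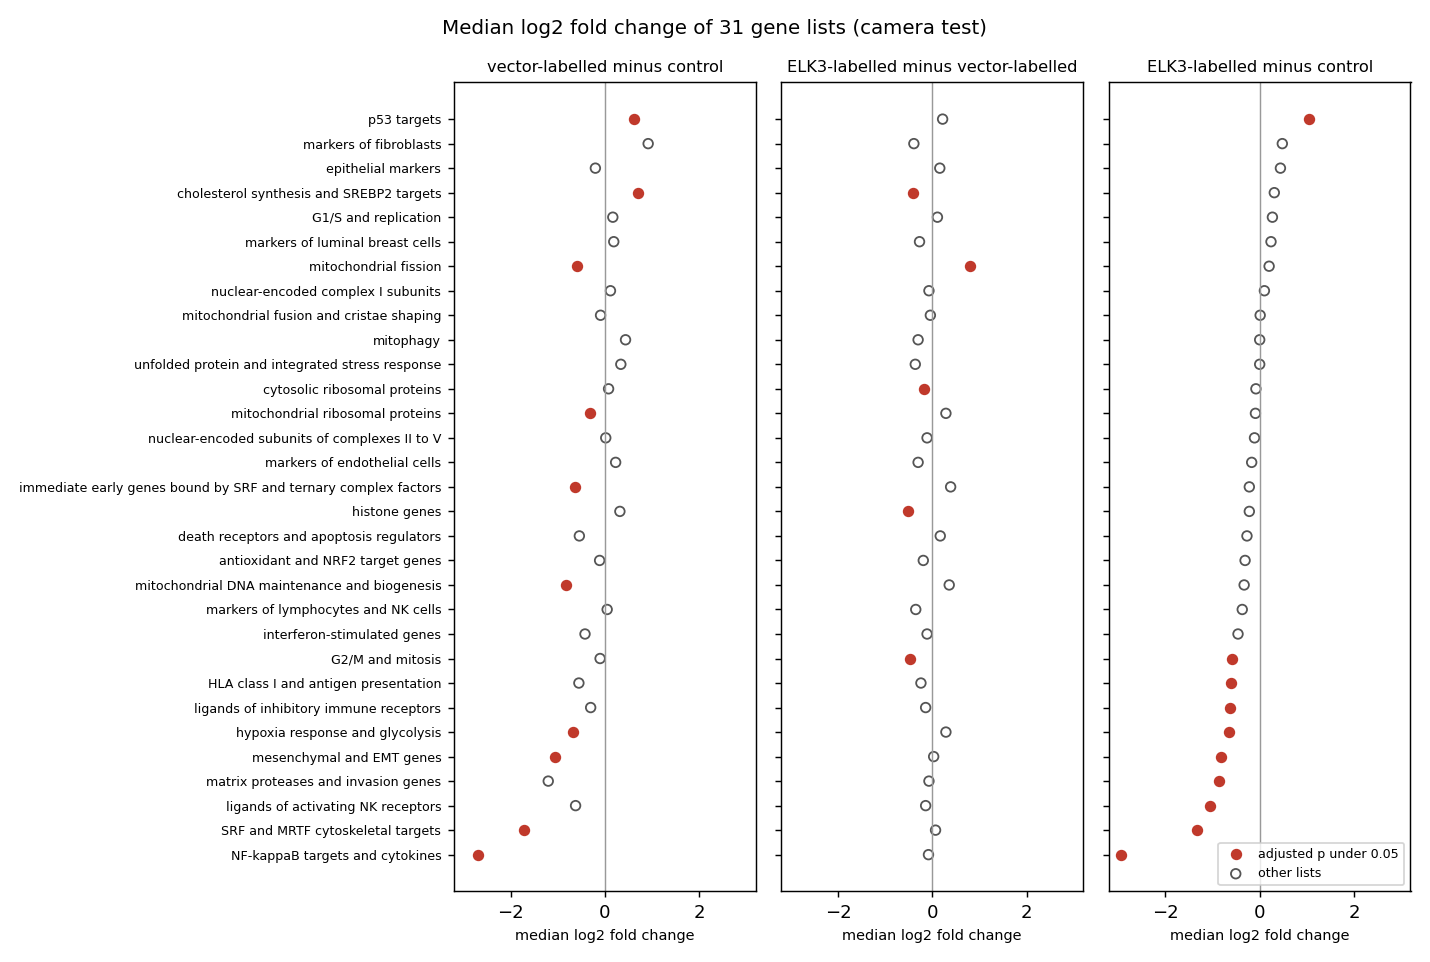
Median log2 fold change of the 31 gene lists in each of the 3 comparisons, with filled points for lists past an adjusted p of 0.05 by camera at a preset correlation. NF-kappaB targets have medians of -2.69 and -2.95 against controls, and 0 lists pass with an estimated correlation, a test on 3 residual degrees of freedom. Library totals in place of TMM raise the median of all genes by 0.13, 0.03 and 0.16, so negative list medians closer to 0 than that have no settled sign.

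**Figure D3:**
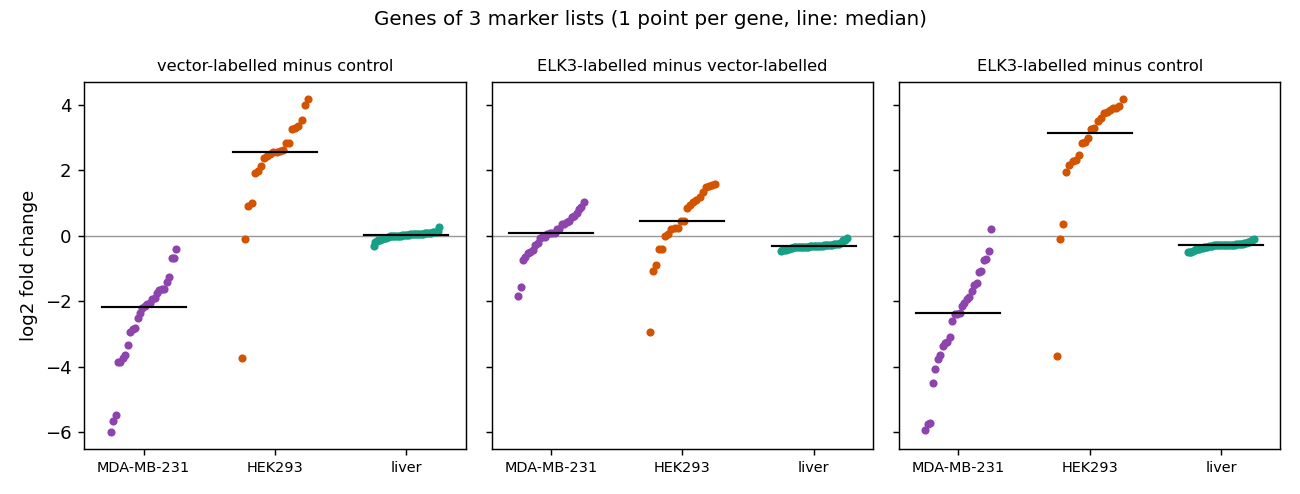
Log2 fold change of each gene of 3 lists chosen after the data were seen, typical of MDA-MB-231 cells, of HEK293 cells and of liver, with a line at each median. Against controls the MDA-MB-231 medians are -2.19 and -2.38 and the HEK293 medians 2.56 and 3.13, and the liver medians are 0.03, -0.32 and -0.29.

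Genes that moved one way in the labelled knockdown and the other way with labelled re-expression were counted across the first 2 comparisons. TRIM43B, TRIM43, RFPL4A, RFPL4AL1 and LINC00368 had 0 to 0.639 CPM in the controls, 12.3 to 38 CPM in the vector-labelled libraries and at most 0.504 CPM in the ELK3-labelled libraries, and at 1 to 8 counts there against 0 to 6 in the controls, 0 of the 5 were called between those groups (adjusted p from 0.423 to 0.93). The ciliary gene BBS10 went from 8.04 to 0.567 and then 4.38 CPM, and ZSCAN9 from 17.9 to 1.84 and 10.5 CPM, with LINC00960, TMEM92 and ADAMTSL5 also lower and then higher. All 5 were still called below the controls in the ELK3-labelled libraries (adjusted p at most 0.0115), with log2 fold changes of -0.93 for BBS10 and -0.77 for ZSCAN9. Calls in opposite directions numbered 6293 (3242 up then down, 3051 down then up) and calls in the same direction 1080 (679 with DESeq2). Independent calls would give 3313.82 and 3314.762. With the labels of the plasmid groups exchanged, an alternative chosen after seeing the data, they numbered 3078 and 2833, where independent calls would give 2872.1 and 2871.6. Both contrasts share the vector-labelled libraries, which makes opposite signs more frequent by itself. In 100 simulations of unchanged groups, where hardly any gene can be called and the count of calls is therefore no guide, log2 fold changes across genes had a mean covariance of -0.028 and a mean correlation of -0.509, against -1.017 and -0.553 observed. Those simulations hold only the spread within groups, so any difference between groups widens the covariance, and the correlations lie close together. In a further alternative chosen after seeing the data, each contrast was given a different vector-labelled library. Opposite calls then numbered 5289 and 5324 in the 2 possible orders, same-direction calls 858 and 867, and the correlation was -0.526 and -0.512. A gene altered in the vector-labelled libraries alone counts as opposite as well, also when each contrast has its own library of that group. Against controls, 7867 genes were called in both other groups, 3560 higher in both, 3633 lower in both and 674 in opposite directions, where 1808.138 and 1673.23 genes higher or lower in both would follow from independent calls. Those contrasts share the controls, and their covariance was 1.893 against 0.031 in the simulations, with a correlation of 0.778 against 0.547. The same limit of the simulations applies, and a gene particular to the controls counts as the same way in both. With a different control library for each contrast, genes higher in both numbered 3014 and 2987, genes lower in both 3244 and 3212, and genes in opposite directions 571 and 584.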

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

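All values here compare with the reported ones under 1 changed setting at a time. With the replicate number as a block, calls were 5650 up and 5407 down, 4579 and 4472, and 4841 and 4690, with 9, 5 and 10 lists and 6215 opposite-direction calls. The replicate numbers gave no sign of pairing (correlations of deviations -0.056, 0.033 and -0.001). Between 76.7% and 99.8%, 78.4% and 99.9%, and 80.7% and 99.6% of the called genes were called the same way under each other setting, and none the other way; a filter of 10 CPM and DESeq2 kept the fewest. Library totals without scaling shifted the median of all genes by 0.13, 0.03 and 0.16 log2 units and gave 6351 up and 4838 down, 4773 and 4372, and 5911 and 3763. Calls in the same direction numbered 679 with DESeq2, against 1080; the cause was not tested. Exchanging the labels of the plasmid groups, chosen after seeing the data, reversed the ELK3 log2 fold changes to -2.54, 5.07 and 2.53 by construction and gave 3078 opposite and 2833 same-direction calls. Of the lists called, 10, 5 and 10, an estimated correlation left 0, 0 and 0. That test rests on 3 residual degrees of freedom and is hard to pass. Fry called 27, 22 and 26 in a direction and 31, 31 and 31 mixed, and fry does not compare a list with other genes. Leaving out a library gave 6 to 11, 3 to 7 and 9 to 10 lists; a lone library was assumed to vary like the others, and the cause was not tested. Of 162 values of named genes, 153 kept their direction and call in every planned setting in which the gene was tested. The exchange of labels and the removal of symbols on several lines were not run on these values. Among those not called, library totals moved MFF to 0.02 in vector-labelled libraries against controls and, in ELK3-labelled libraries against controls, HLA-C to 0.02, FIS1 to 0.16 and MFF to 0.34, past the threshold; FIS1, reported at 0, also stood at 0.03 with a filter of 10 CPM, at 0 with no filter or only 4 libraries, and from -0.08 to 0.06 without a library. Depth limits genes under 0.614 CPM, 3 counts in the shallowest library. Pseudocount settings were not run on counts.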

Other observations

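The tests of list genes chosen as typical of MDA-MB-231, HEK293 and liver, and all tests of explanations, were chosen after the results were seen; the gene lists of the first paragraphs were fixed before.

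Respiratory chain genes moved both ways. Complex I subunits had 16 up and 11 down of 37 in vector-labelled libraries against controls (adjusted p = 0.59), and complexes II to V 17 up and 15 down of 39 (adjusted p = 0.981). The cytochrome oxidase subunit gene COX7B rose from 177.1 to 578.3 CPM and COX8A fell from 716.5 to 348.1 CPM. Mitophagy genes had 10 up and 6 down of 19 (adjusted p = 0.506), with PINK1, the kinase that marks damaged mitochondria, at 1.49 ± 0.13 and the receptor OPTN at -1.55 ± 0.1. Antioxidant genes had 9 up and 12 down of 25 (adjusted p = 0.505, median -0.11, and 0.02 with library totals), with the NRF2 target NQO1 falling from 163.7 to 11.7 CPM and SOD2, the mitochondrial superoxide dismutase, rising by 0.8 ± 0.1. Unfolded protein response genes had 17 up and 8 down of 31 (adjusted over the list alone 17 and 10, adjusted p = 0.363), with PHGDH, the first enzyme of serine synthesis, rising by 3.2 ± 0.12. Epithelial markers had 11 up and 11 down of 23 (adjusted p = 0.796), with CLDN4 at -4.82 ± 0.19 and JUP at 3.25 ± 0.14. Matrix protease genes had 13 down and 7 up of 22 there (adjusted p = 0.0613).

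Death receptor and apoptosis genes had 16 down and 8 up of 29 in the same comparison (adjusted p = 0.177), with the death receptor gene TNFRSF10B falling from 94.4 to 25.8 CPM. Interferon-stimulated genes had 18 down and 8 up of 37 (adjusted p = 0.262), with BST2, or tetherin, at 2.45 ± 0.12. Ligands of inhibitory receptors had 7 down and 1 up of 13 (adjusted p = 0.177), with CD274, or PD-L1, falling from 11.9 to 1.26 CPM. Replication genes had 15 up and 10 down of 38 (adjusted p = 0.59), G2/M genes 12 up and 17 down of 38 (adjusted p = 0.528, median -0.1, and 0.03 with library totals), histones 11 up and 9 down of 22 (adjusted p = 0.505) and cytosolic ribosomal proteins 31 up and 20 down of 78 (adjusted p = 0.59). Lymphocyte markers had 3 up of 21 (adjusted p = 0.645), luminal markers 5 up and 3 down of 11 (0.59), fibroblast markers 4 up of 8 (0.262) and endothelial markers 2 up and 3 down of 10 (0.981, tested as lower at a median of 0.23 and a mean of -0.21). The median of complexes II to V was 0.02 and the mean of fusion and cristae genes 0.03, both opposite in sign to a test that leaned lower.

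ELK3 ran against the labels in the 4 plasmid libraries. Knockdown and re-expression with the labels as given would put ELK3 higher in the ELK3-labelled than in the vector-labelled libraries, and a plasmid transcript that was not counted would by itself leave them alike, but the difference was -5.07 log2 units. That difference does not settle whether plasmid transcripts were counted, since the prediction assumes that nothing else differs between the plasmid groups. An exchange of the labels of the knockdown groups stays open without a test of its own, since the ELK3 log2 fold changes over controls that it needs, 2.53 and -2.54, are the values that prompted it. Those changes also assume controls of the same line, where genes typical of MDA-MB-231 cells had medians of -2.19 and -2.38. The labels name no biological change that would raise ELK3 in a knockdown, and none was tested.

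Genes typical of MDA-MB-231 cells were lower in both plasmid groups, though 23 and 23 of 28 still reached 5 CPM. If those genes followed the level of ELK3 and the controls were the same line, they would move in opposite directions in the groups. Of 22 list genes not looked at before, 21 fell in both. A response that lowers them at either level of ELK3 was not tested. Of all 28, 8 stand in lists fixed before. A lasting change within MDA-MB-231 cells would leave CDKN2A near its control level of 15.5 CPM. This gene lies in a region on chromosome 9 known to be lost from the line. It rose to 217.9 and 174.7 CPM, by at least 3.49 log2 units. Of 3 genes tested from that region, 3 rose in both plasmid groups. They were counted in the controls too, at 146 (CDKN2A), 35 (MTAP) and 11 (CDKN2B) counts over both libraries. Why a lost region was counted there was not tested. Cells of another line may be present: of HEK293-typical genes not looked at before, 15 in number, the medians were 2.48 and 2.85, above all of 10000 random lists, though 10 of the whole list's genes also reached 5 CPM in the controls. Between the plasmid groups the median of these 15 genes was 0.84, and 8 of 10000 random lists were as high. For the 22 MDA-MB-231-typical genes not looked at before it was 0.2 there, with 1936 random lists as high. UCHL1, CKB and IGF2BP1 had the smallest p of the HEK293 list in vector-labelled libraries against controls. They had 671.7, 501.5 and 126 CPM in the vector-labelled libraries against 41.9, 115.4 and 21.3 in the controls. The line itself was not identified by a profile, so other lines with such genes stay open.

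Liver transcripts stood in every library, with 1.46% to 1.87% of all counts on 42 genes. Expression by the cultured cells was tested by the share of these genes called. It was 2.4% in the vector-labelled libraries against controls, compared with 72.3% of all genes. In the ELK3-labelled libraries against vector-labelled ones and controls, 32 and 34 of 42 were called lower, compared with 59.6% and 62.6% of all genes. That share did not decide, but those calls were a near-uniform shift, with 0 called higher. For 13 liver genes not looked at before, SDs of the log2 fold changes were 0.11, 0.09 and 0.12 in the 3 comparisons. The smallest SDs of 10000 random lists were 0.44, 0.27 and 0.28. These values argue against expression that the cultured cells regulate gene by gene. A fixed number of foreign reads per library would give equal counts in both ELK3-labelled libraries, and their ratio was 1.57 at a depth ratio of 1.53. The bounds of this test and of the test by share called were revised after the values were seen. For the fixed number, a first form, which asked for an interval that held the depth ratio, did not decide. Foreign reads that rise in number with depth were not tested, and the SDs of the liver genes cannot tell them from foreign RNA. Foreign RNA that holds liver transcripts in a fixed ratio may be a source, since the SD of the log2 fold changes of liver genes not looked at before was at most 0.12, below all of 10000 random lists. Whether it held liver RNA alone was not tested: the lymphocyte genes GZMA (44.8, 46.4 and 34 CPM) and PTPRC (31.4, 35 and 24.2 CPM) stood in all 3 groups, with list medians of 0.05, -0.35 and -0.37 beside 0.03, -0.32 and -0.29 for liver, and the labels name no sample of either kind.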
